A study of Mus musculus and Rattus norvegicus with 85 samples.

How the data were processed

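RNA from the right lung of 85 female animals was measured on Affymetrix mouse and rat whole-genome arrays, 1 array per animal with nothing pooled: 45 B6C3F1/Crl mice in 9 groups and 40 F344/NCrl rats in 8 groups of 5. The animals were exposed whole-body to chloroprene vapour for 5 or 15 exposure days. Per the labels, total RNA was extracted with Trizol and RNeasy columns and labelled with biotin by the standard Affymetrix protocol. The deposited values are log2 signals per probe set, summarized and normalized by the authors with methods the sources used here do not give. The values ran from 3.47 to 15.3 in the mouse and from 3.07 to 15.1 in the rat. The number of arrays limits the precision: the median standard error of a change was 0.0991 in the mouse and 0.110 in the rat on the log2 scale.

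Of 45101 mouse probe sets, 34958 carried 1 gene symbol, 932 several and 9211 none; of 31099 rat probe sets these counts were 20832, 436 and 9831. The mouse names were checked by Entrez identifier against a RefSeq gene table, which matched 34754. That table holds mouse genes, so the rat names were used as the array annotation gives them. Probe sets with several symbols or none and control probe sets (64 in the mouse, 57 in the rat) were left out of the comparisons. A probe set was kept where its signal exceeded the 40th percentile of its species' table (6.67 in the mouse, 6.65 in the rat) on at least 5 arrays, which kept 24434 and 15109 named probe sets. Each gene was represented by its kept probe set with the highest mean, which gave 13796 mouse and 11010 rat genes.

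Animals were grouped by species, concentration and exposure days as in the sample titles. For 9 mice of the 15-day groups the duration field of the labels conflicts with the title, 6 mice have a letter after the animal number in the title, 3 rats have a title without the tissue, and 7 arrays have no RNA integrity number. All 85 arrays were used. Each species was fitted alone with limma 3.58.1 in R 4.3.3, with a mean per group and empirical Bayes moderation, and p-values were adjusted by Benjamini-Hochberg over all genes of a comparison at a threshold of 0.05, two-sided. There were 15 comparisons: each concentration against 0 ppm (mouse, 5 days) or against the lowest concentration of the same time, and in each species the difference between the times in the change from the lowest shared to the highest concentration. Changes of at least 1.5-fold were counted besides.

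The comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The 38 lists, with 886 genes in all, cover pathways, lung cell types and neighbouring tissues and were written from textbook knowledge. Lists with at least 5 measured members were tested with limma's camera at a preset correlation between genes of 0.01, and again with an estimated correlation, adjusted over the lists of a comparison. The mean log2 value of a list's members, each centred over all arrays of the species, gave a score per array. Named genes were the 10 largest rises and 10 largest falls past the threshold in each of the 4 comparisons of the highest concentration, leaving out symbols of unnamed models, up to 4 members by smallest p of each list that passed, and the genes Cyp2e1, Cyp2f2 or Cyp2f4, Ephx1, Gclc, Gclm, Nqo1, Hmox1, Scgb1a1, Mki67 and Cdkn1a whatever their result. For the other comparisons they were the 3 largest rises and 3 largest falls past the threshold, for the differences between times the 5 with the smallest p in each direction, and where none passed the 3 with the smallest p.

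Overlaps of called genes were tested with the two-sided Fisher exact test over genes tested in both sets, and species were matched by identical symbol. Differences between 2 groups of single values were tested by exact permutation, two-sided. For the RNA integrity number, the difference between the 3' and 5' control probe sets for Gapdh and beta-actin, and the mean of the bacterial poly-A spike-in controls, correlations with the between-array score were computed within groups over all arrays of a species, with Pearson's r and Spearman's rho and permutation p from 1e+05 resamples, for 6 relations. The between-array score is the first component of the residuals from the group means.

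Alternatives fixed in advance were no filter, a filter at the 60th percentile, quantile normalization, the mean of all kept probe sets of a gene, the RNA integrity number or the 3' to 5' difference as covariate, arrays of the same time only, a variance trend with robust moderation, leaving out the mice with conflicting durations or lettered numbers, the 0.3 ppm mice as reference, leaving out each animal in turn, the other probe sets of a named gene and, for overlaps, calls of at least 1.5-fold. Alternatives chosen after seeing the data were the between-array score as covariate, that score computed in the rat with the weights from the mouse arrays, the letter after the animal number as a block, and leaving out the 3 rats whose title lacks the tissue. For each comparison 100 splits of its arrays into groups of the same sizes, the real one included, were fitted (seed 1). Groups of 5 were searched for a value far from the others by Dixon's ratio at 0.71. Tables were also read with the R package data.table (1.17.8), and figures were drawn in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

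The pipeline was tested on simulated data, with independent noise of each gene's own residual spread. Real arrays share a pattern of variation, so the error rates below need not hold for them. In the mouse, 85% of genes shifted by 0.5 and 100% of those shifted by 1 on the log2 scale were called, with 3.65% false calls; in the rat these shares were 67%, 98% and 4.07%. A list shifted by 0.3 was found in both species, with 0 false lists. With a planted between-array pattern fitted as covariate, 92.5% of the changed genes were called in the mouse and 81.5% in the rat.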

Results

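The 85 arrays measured mRNA in the right lung of female B6C3F1/Crl mice and F344/NCrl rats that breathed chloroprene, the chlorinated monomer of neoprene rubber, as vapour for 6 h per day on 5 days per week. The mouse groups were 0, 0.3, 2, 13 and 90 ppm after 5 exposure days and 0.3, 2, 13 and 90 ppm after 15. The rat groups were 5, 30, 90 and 200 ppm after 5 and after 15 exposure days. Each held 5 animals with 1 array each, which limits the precision. No mouse group at 0 ppm after 15 days and no rat group at 0 ppm was analysed. The lowest concentration was the reference there, and a change already present at it was not measured. In all, 13796 genes were tested in the mouse and 11010 in the rat. Changes are log2 differences between group means ± the standard error of the limma fit, with n = 5 animals per group. A gene rose or fell where its adjusted p passed 0.05. For a list that passed, 2 adjusted p are given, the first with a preset and the second with an estimated correlation between genes, and "list alone" marks counts adjusted over the list alone.

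In the mouse, 90 was compared with 0 ppm after 5 days. Several large rises were in enzymes that detoxify reactive compounds. Aldh3a1, an aldehyde dehydrogenase, rose 8.79-fold (3.14 ± 0.17, adjusted p = 6.5e-17). Ces1g, a carboxylesterase, rose 8.34-fold (3.06 ± 0.18, adjusted p = 2.0e-16) and Cbr3, a carbonyl reductase, rose 5.24-fold (2.39 ± 0.12, adjusted p = 3.5e-18). Fkbp5, a chaperone of the glucocorticoid receptor, rose 7.53-fold (2.91 ± 0.42) and the transcription factor Zbtb16, which glucocorticoids induce, rose 7.95-fold (2.99 ± 0.53, adjusted p = 8.1e-05). Among the falls, Ms4a1, which encodes the B cell antigen CD20, fell by 1.74 ± 0.30, Cd69, an activation antigen of lymphocytes, fell by 1.62 ± 0.19, and Nr1d1, a repressor of the circadian clock, fell by 1.72 ± 0.22. In each of the 5 exposed mice all of these genes lay beyond every one of the 5 reference mice.

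Of 22 measured targets of NRF2, the transcription factor of the response to oxidants and electrophiles, 21 rose and 0 fell (list alone 21 and 0; adjusted p = 3.9e-43 and 2.2e-05). They included Nqo1, a quinone reductase (2.17 ± 0.13, 4.49-fold), Gpx2, a glutathione peroxidase (1.97 ± 0.12), and both subunits of the enzyme that limits glutathione synthesis, Gclm (1.55 ± 0.09) and Gclc (1.41 ± 0.13). Of 25 genes of glutathione synthesis and conjugation, 13 rose and 0 fell (list alone 16 and 0; adjusted p = 2.7e-15 and 0.011). Among them were the transferases Gsta2 (2.15 ± 0.15) and Gsto1 (1.31 ± 0.10) and glutathione synthetase, Gss (1.05 ± 0.08). Of 22 genes of the first phase of xenobiotic metabolism, 15 rose and 1 fell (list alone 15 and 2; adjusted p = 4.1e-12 and 0.019). Aldehyde oxidase, Aox1, rose by 1.43 ± 0.12 and Ephx1, the microsomal epoxide hydrolase, by 0.64 ± 0.05. Cyp2e1, a cytochrome P450 that oxidizes small chlorinated compounds, rose by 0.88 ± 0.29 (adjusted p = 0.031, above all reference mice in 3 of 5). Cyp2f2, the P450 typical of club cells, was at 0.06 ± 0.04 (adjusted p = 0.32). The haem oxygenase Hmox1 rose by 0.57 ± 0.15 (adjusted p = 0.0063). Metallothioneins, which bind metal ions, rose as well: Mt2 by 1.90 ± 0.15 and Mt1 by 1.46 ± 0.14, although the second probe set of Mt1 was at -0.01.

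**Figure D1:**
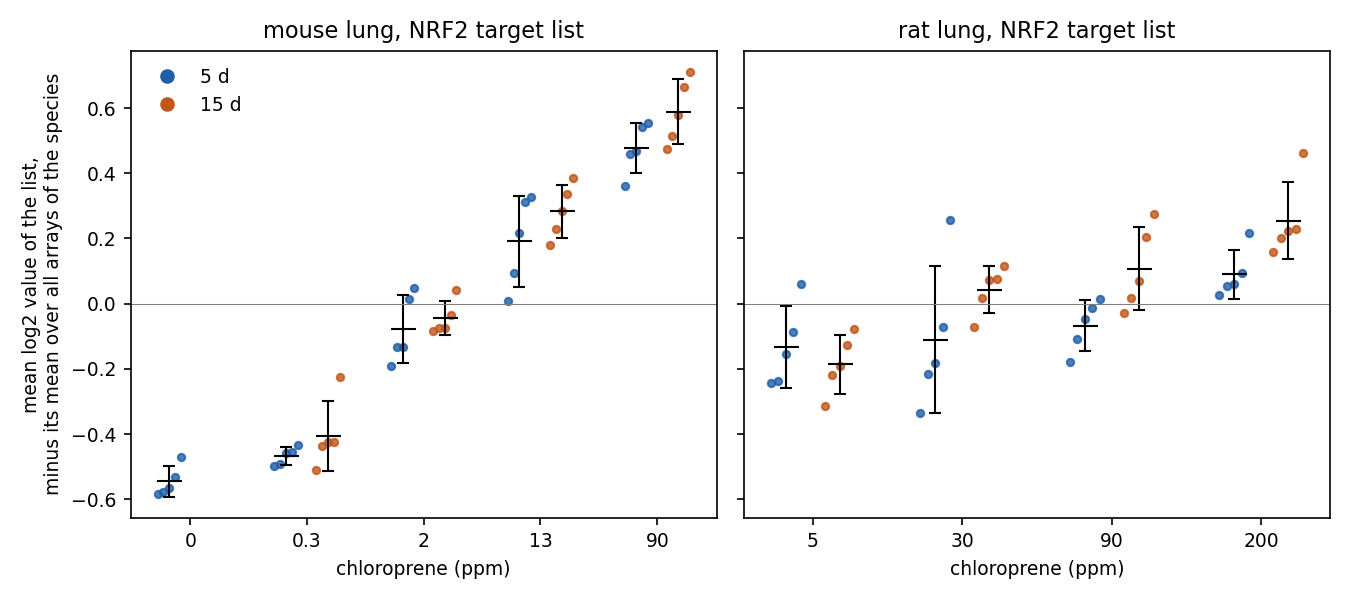
Mean score of the NRF2 target list (log2, relative to the mean over all arrays of the species) against chloroprene concentration, by species and exposure time, where points are animals and bars the mean ± SD of 5 animals. The mouse means at 5 days step from -0.54 at 0 ppm to 0.48 at 90 ppm, and the rat means at 5 days from -0.13 at 5 ppm to 0.09 at 200 ppm.

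Lists of epithelial and dividing cells also shifted in these mice. Of 27 genes of ciliated cells, 18 rose and 0 fell (list alone 21 and 0; adjusted p = 4.1e-12 and 0.21). The tektin Tekt1 (0.70 ± 0.11) and the radial spoke gene Rsph9 (0.72 ± 0.12) were among the rises. Of 17 genes of club cells, the secretory cells of the airways, 7 rose and 0 fell (list alone 9 and 1; adjusted p = 1.0e-05 and 0.18). Selenbp1 (0.65 ± 0.08) and Aldh1a1 (0.41 ± 0.06) were among them, and the club cell marker Scgb1a1 was at -0.10 ± 0.04 (adjusted p = 0.051). The group means of Scgb1a1 (15.16 and 15.26) lay near the highest mouse signal of 15.3, where a change can be compressed, so an unchanged marker was not shown in either species. Of 44 cell cycle genes, 12 rose and 0 fell (list alone 12 and 0; adjusted p = 0.00096 and 0.52). The mitotic kinases Nek2 (1.15 ± 0.14), Cdk1 (0.93 ± 0.16) and Aurka (0.80 ± 0.12) rose, and Mki67, a marker of proliferation, was at 0.05 ± 0.24. Of 21 targets of p53, 6 rose and 1 fell (list alone 6 and 2; adjusted p = 0.019 and 0.15). Cdkn1a, an inhibitor of the cell cycle, rose by 1.27 ± 0.17, and Plk2 fell by 0.93 ± 0.20, with its other probe set at 0.13. Of 18 genes that glucocorticoids regulate, 9 rose and 1 fell (list alone 10 and 1; adjusted p = 1.1e-05 and 0.21). Genes of alveolar type 2 cells, which make surfactant, had 1 rise and 6 falls among 18 (list alone 1 and 8; adjusted p = 0.0011 and 0.22). Genes of alveolar type 1 cells had 0 and 3 among 16 (list alone 0 and 3; adjusted p = 0.019 and 0.38). Cxcl15, a lung chemokine (-0.51 ± 0.05), and the water channel Aqp5 (-0.29 ± 0.08) were among these falls.

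Immune and matrix lists declined. Of 19 genes of B and plasma cells, 0 rose and 15 fell (list alone 0 and 17; adjusted p = 5.9e-11 and 0.15). Among the falls were Ms4a1, the adaptor Bank1 (-1.42 ± 0.24) and the coactivator Pou2af1 (-1.51 ± 0.34). Of 22 genes of T and natural killer cells, 0 rose and 15 fell (list alone 0 and 17; adjusted p = 1.3e-09 and 0.22). Cd3g, part of the T cell receptor complex, fell by 1.20 ± 0.22, the killer cell receptor Klrd1 by 1.11 ± 0.22, and Ms4a4b by 1.57 ± 0.27, with another probe set of Ms4a4b at 0.01. Of 9 genes of MHC class II antigen presentation, 0 rose and 6 fell (list alone 0 and 8; adjusted p = 3.5e-05 and 0.22). Of 29 interferon response genes, 0 rose and 8 fell (list alone 0 and 11; adjusted p = 1.0e-05 and 0.28), such as the GTPase Gbp2 (-0.69 ± 0.12). Of 16 inflammatory cytokines and their partners, 1 rose and 4 fell (list alone 1 and 5; adjusted p = 0.031 and 0.28). The chemokine Ccl20 was at 0.66 ± 0.12 and the alarmin Il33 at -0.73 ± 0.15. Of 28 immediate early genes, 3 rose and 6 fell (list alone 5 and 13; adjusted p = 0.0078 and 0.36). The nuclear receptor Nr4a1 was at -1.55 ± 0.38 and the phosphatase Dusp1 at -0.80 ± 0.19. Of 25 genes of fibroblasts and their matrix, 1 rose and 6 fell (list alone 1 and 6; adjusted p = 0.0070 and 0.52). The matrix gene for tenascin C, Tnc, fell by 1.36 ± 0.23 and the collagen gene Col3a1 by 0.74 ± 0.24. Of 20 genes of cholesterol synthesis, 0 rose and 9 fell (list alone 1 and 12; adjusted p = 1.2e-06 and 0.14), such as Cyp51 (-0.67 ± 0.10) and Sc5d (-0.74 ± 0.12).

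**Figure D2:**
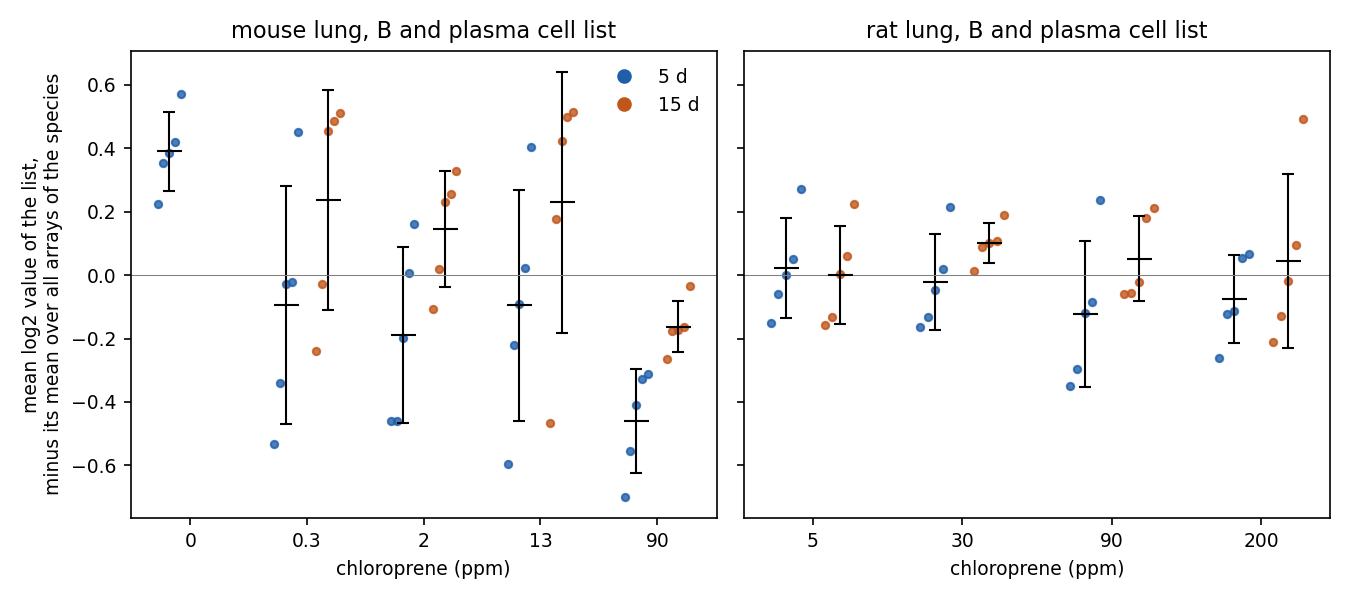
Mean score of the B and plasma cell list (log2, relative to the mean over all arrays of the species) against chloroprene concentration, by species and exposure time, where points are animals and bars the mean ± SD of 5 animals. After 5 days the mouse means are 0.39 at 0 ppm, -0.09 at 0.3 ppm and -0.46 at 90 ppm, and the rat means 0.02 at 5 ppm and -0.08 at 200 ppm.

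limma called 2254 genes in this comparison, 1240 of them higher and 1014 lower, and 577 by at least 1.5-fold. With the 0.3 ppm mice as reference 1360 genes passed, and 1178 of the 2254 kept their call; among the genes named above, Zbtb16, Hmox1, Cyp2e1, Aqp5, Col3a1, Pou2af1, Nr4a1, Dusp1 and Plk2 lost theirs. Of the 18 list calls 14 were kept, and those of p53 targets (adjusted p = 0.24), alveolar type 1 cells (0.16), cytokines (0.26) and immediate early genes (0.080) ended, while endoplasmic reticulum stress (-0.15, adjusted p = 0.0073) and heat shock (-0.51, 0.00011) passed as lower. With the RNA integrity number as a covariate, which left 2 of the 5 reference mice, 761 genes passed; the list calls of fibroblast matrix (adjusted p = 0.13), alveolar type 1 cells (0.24) and cytokines (0.12) ended, and mucous cells (0.57, adjusted p = 0.018) and cardiac muscle (0.42, 0.044) passed. Cytokines also ended with the 3' to 5' difference (0.054), adipose tissue passed with arrays of the same time (0.022) or without the lettered mice (0.020), and mucous cells passed without a filter (0.027). The lists that did not pass were those of mucous cells (adjusted p = 0.077), hypoxia (0.090), adipose tissue (0.096), thymus (0.099), cardiac muscle (0.18), neutrophils (0.20) and endothelium (0.20). Others were smooth muscle (0.27), fatty acid oxidation (0.30), erythroid cells (0.33), basal cells (0.55), endoplasmic reticulum stress (0.65), the circadian clock, alveolar macrophages and heat shock (0.73 each), skeletal muscle, DNA repair, mast cells and oxidative phosphorylation (0.77 each) and lipogenesis (0.79).

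At 13 against 0 ppm after 5 days limma called 179 genes, 161 higher and 18 lower, and 64 by at least 1.5-fold. Ces1g rose by 2.05 ± 0.18 (adjusted p = 9.6e-11), Cbr3 by 1.73 ± 0.12 (adjusted p = 2.8e-13) and Zbtb16 by 2.45 ± 0.53 (adjusted p = 0.0083). Nr4a1 fell by 1.55 ± 0.38, the chemokine receptor Cxcr4 by 0.75 ± 0.20, and the chemokine scavenger Ackr4 by 0.56 ± 0.14, with the other probe sets of Ackr4 at 0.14 and 0.06. At 2 ppm, 166 genes passed, 147 higher and 19 lower, and 56 by at least 1.5-fold. Zbtb16 (2.28 ± 0.53, adjusted p = 0.024), the airway secretory gene Bpifb1 (1.93 ± 0.51, adjusted p = 0.047) and the heat shock gene Hspa1a (1.89 ± 0.46, adjusted p = 0.028) rose. The B cell genes Ms4a1 (-1.19 ± 0.30, adjusted p = 0.036) and Ighv14-2 (-1.45 ± 0.39, adjusted p = 0.049) and the T cell gene Ms4a4b (-1.03 ± 0.27, adjusted p = 0.046) fell. NRF2 targets rose at both concentrations, 18 of 22 at 13 ppm (list alone 20; adjusted p = 3.6e-67 and 2.1e-07). At 2 ppm 16 of 22 rose (list alone 17; adjusted p = 4.9e-32 and 0.00029). At 0.3 ppm limma called 0 genes, with 514 at an unadjusted p under 0.05. The 3 genes with the smallest p there were Zbtb16 (2.31 ± 0.53), Jade2 (0.50 ± 0.12) and Rhobtb1 (0.44 ± 0.10), each with adjusted p = 0.58. The mean change of the NRF2 targets at 0.3 ppm was 0.08 (adjusted p = 0.0018 and 0.41; 0 members rose). Against the 0.3 ppm mice, 11 genes passed at 2 ppm and 48 at 13 ppm; the 6 genes named at 2 ppm lost their calls and Zbtb16 was at -0.04. Without mouse 136 of the 2 ppm group 34 genes passed at 2 ppm, and without mouse 151 of the 13 ppm group 81 passed at 13 ppm.

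After 15 days, 90 was compared with 0.3 ppm in the mouse. Aldh3a1 rose 6.32-fold (2.66 ± 0.17, adjusted p = 8.3e-15), Ces1g 5.81-fold (2.54 ± 0.18), Nqo1 5.12-fold (2.36 ± 0.13, adjusted p = 5.1e-17) and Cbr3 4.61-fold (2.21 ± 0.12). Fkbp5 (2.36 ± 0.42), the vesicle protein gene Doc2b (2.04 ± 0.19), Myrip, which links vesicles to myosin (1.98 ± 0.20), and Gp2, a receptor for bacteria on epithelial cells (1.43 ± 0.28), rose too. Mmp11, a matrix metalloproteinase, fell by 1.05 ± 0.19, Ccn5, a secreted matrix protein gene, by 1.09 ± 0.20, Rasgrp3, an activator of Ras, by 1.06 ± 0.17, and the peroxisomal oxidase gene Acoxl by 1.00 ± 0.16. The heat shock genes Hspa1a (-1.57 ± 0.46, adjusted p = 0.026) and Hspa1b (-1.55 ± 0.43, adjusted p = 0.016) fell, each below all reference mice in 3 of 5.

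NRF2 targets again rose together, 18 of 22 with 0 falls (list alone 20 and 0; adjusted p = 1.9e-62 and 4.9e-07). Gclc (1.57 ± 0.13), Gclm (1.54 ± 0.09), the thioredoxin reductase Txnrd1 (1.23 ± 0.08) and Hmox1 (0.97 ± 0.15) were among them. Of the glutathione genes 12 of 25 rose and 0 fell (list alone 13 and 1; adjusted p = 1.6e-18 and 0.0037). These rises included Gsta2 (2.11 ± 0.15), Gsto1 (1.15 ± 0.10) and Gstm1 (0.63 ± 0.05). Of the genes of first-phase metabolism 11 of 22 rose and 0 fell (list alone 14 and 0; adjusted p = 1.2e-15 and 0.0046). Aox1 was at 1.32 ± 0.12 and Ephx1 at 0.50 ± 0.05, whereas Cyp2e1 (0.13 ± 0.29, adjusted p = 0.89) and Cyp2f2 (0.05 ± 0.04, adjusted p = 0.53) did not pass. Of the p53 targets 6 of 21 rose and 0 fell (list alone 7 and 2; adjusted p = 0.0018 and 0.039). Cdkn1a rose by 0.70 ± 0.17, Mdm2, which limits p53, by 0.40 ± 0.10, and Sesn1 by 0.31 ± 0.08. Genes of ciliated cells rose, 13 of 27 with 0 falls (list alone 19 and 0; adjusted p = 2.5e-13 and 0.15), with Dynlrb2 at 0.68 ± 0.12 and Tekt1 at 0.48 ± 0.11. Of the club cell genes 5 of 17 rose and 0 fell (list alone 6 and 0; adjusted p = 3.0e-06 and 0.13), while Scgb1a1 was at -0.02 ± 0.04 (adjusted p = 0.83). Glucocorticoid genes had 8 rises and 0 falls among 18 (list alone 8 and 1; adjusted p = 1.1e-06 and 0.14), Zbtb16 at 1.94 ± 0.53 (adjusted p = 0.017). Mucous cell genes had 2 rises and 1 fall among 10 (list alone 3 and 1; adjusted p = 0.0054 and 0.31), with the trefoil factor Tff2 at 1.01 ± 0.26.

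Lists of lipid synthesis and of immune cells were lower in these mice, and each of the calls that follow was lost with an estimated correlation. Cholesterol synthesis had 0 rises and 6 falls among 20 (list alone 0 and 14; adjusted p = 4.0e-07 and 0.079), with Cyp51 at -0.60 ± 0.10. Lipogenesis had 0 and 5 among 19 (list alone 0 and 6; adjusted p = 0.00074 and 0.25). The falls included Fasn, the fatty acid synthase (-0.58 ± 0.13), and Acaca (-0.42 ± 0.12), whose other probe set was at 0.10. Fatty acid oxidation had 1 and 3 among 19 (list alone 2 and 6; adjusted p = 0.011 and 0.49). The lipoprotein lipase inhibitor Angptl4 was at 0.85 ± 0.18 and the lipid droplet gene Plin2 at -0.50 ± 0.08. Alveolar type 2 genes had 1 and 5 among 18 (list alone 1 and 9; adjusted p = 3.4e-05 and 0.12), with Etv5, a transcription factor of these cells, at -0.63 ± 0.17. T and natural killer cell genes had 0 and 3 among 22 (list alone 0 and 8; adjusted p = 1.1e-05 and 0.35). The chemokine Ccl5 fell by 0.81 ± 0.24, granzyme A, Gzma, by 0.91 ± 0.25 and Ncr1 by 0.67 ± 0.20. B and plasma cell genes had 0 and 1 among 19 (list alone 0 and 4; adjusted p = 8.2e-05 and 0.35), Spib at -0.76 ± 0.22. MHC class II genes had 0 and 3 among 9 (list alone 0 and 7; adjusted p = 2.0e-05 and 0.24), with the transactivator Ciita at -0.49 ± 0.12. Interferon genes had 0 and 6 among 29 (list alone 0 and 11; adjusted p = 1.5e-05 and 0.30), with Gbp2 at -0.58 ± 0.12. Cell cycle genes, with 1 rise and 1 fall among 44 (list alone 1 and 0), passed as lower (adjusted p = 0.0024 and 0.51). The remaining lists that passed as lower were skeletal muscle (0 and 1 of 11, adjusted p = 0.0020 and 0.30), adipose tissue (0 and 0 of 10, adjusted p = 0.012 and 0.49) and immediate early genes (0 and 2 of 28, adjusted p = 0.012 and 0.39). Others were cytokines (1 and 2 of 16, adjusted p = 0.018 and 0.26), heat shock (0 and 2 of 18, adjusted p = 0.026 and 0.59), oxidative phosphorylation (0 and 0 of 26, adjusted p = 0.027 and 0.61) and fibroblast matrix (1 and 2 of 25, adjusted p = 0.045 and 0.59). Adjusted over the list alone, their rises and falls were 0 and 3, 0 and 0, 0 and 3, 1 and 4, 0 and 2, 0 and 0, and 1 and 3, in that order. Without the mice whose labels give conflicting durations, adipose tissue turned to higher (0.39, adjusted p = 0.019), as did oxidative phosphorylation (0.09, adjusted p = 0.0086), fatty acid oxidation (0.20, adjusted p = 0.13) and skeletal muscle (0.09, adjusted p = 0.70). Without the lettered mice all of these but skeletal muscle turned without passing. Fatty acid oxidation and oxidative phosphorylation did so without mouse 127 of the 0.3 ppm group, so the direction of these lists depended on the mice used. The adipose members Ucp1, the uncoupling protein of brown fat (-2.25 ± 0.85, adjusted p = 0.10), and Cidea (-1.29 ± 0.60, adjusted p = 0.22) did not pass.

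limma called 1100 genes after 15 days, 646 higher and 454 lower, and 278 by at least 1.5-fold. Without the mice with conflicting durations, which include all lettered mice of these groups, 530 genes passed, and without the lettered mice alone 501 did. Hspa1a, Hspa1b, Zbtb16, Tff2, Ccl5, Gzma, Ncr1, Spib, Ciita, Fasn, Acaca and Etv5 lost their calls in both, and Mdm2, Sesn1 and Cyp51 lost theirs without the mice with conflicting durations. Of the 24 list calls 17 were kept in the same direction under each of these alternatives. Lipogenesis had means above 0 (0.04 without the mice with conflicting durations, 0.01 without the lettered mice), so its direction depended on the mice too. It lost its call, as did immediate early genes (-0.19 in both) and cytokines (-0.12, without the mice with conflicting durations). Skeletal muscle (0.00050) and fibroblast matrix (-0.10) lost theirs without the lettered mice. Lists that passed only under an alternative were alveolar type 1 cells (-0.19, adjusted p = 0.0023), endothelium (-0.17, 0.0017) and cardiac muscle (0.75, 0.0023) without the mice with conflicting durations, and alveolar type 1 cells (-0.12, 0.033) and cardiac muscle (0.46, 0.015) without the lettered mice. Neutrophils passed as lower without a filter (adjusted p = 0.049), with the 60th percentile (0.023) and with arrays of the same time (0.049), and thymus without a filter (0.027). Oxidative phosphorylation and fibroblast matrix lost their calls with quantile normalization (0.055 and 0.056) and the between-array score (0.073 and 0.11), and oxidative phosphorylation with arrays of the same time (0.059). The lists that did not pass were those of neutrophils (adjusted p = 0.073), alveolar type 1 cells (0.089), thymus (0.11), circadian clock (0.11), alveolar macrophages (0.13) and endothelium and smooth muscle (0.14 each). Others were erythroid cells (0.39), hypoxia and cardiac muscle (0.48 each), DNA repair, basal cells and mast cells (0.52 each) and endoplasmic reticulum stress (0.60).

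At 13 against 0.3 ppm after 15 days limma called 45 genes, 44 higher and 1 lower, and 27 by at least 1.5-fold. Ces1g rose by 1.80 ± 0.18 (adjusted p = 3.4e-09), Nqo1 by 1.70 ± 0.13 (adjusted p = 7.2e-12) and Aldh3a1 2.83-fold. Cep57l1, which encodes a centrosomal protein, fell by 0.29 ± 0.07 (adjusted p = 0.042), although other probe sets of Cep57l1 were at 0.05 and 0.11. NRF2 targets rose at 13 ppm, 17 of 22 (list alone 19; adjusted p = 5.6e-87 and 9.7e-09). So did 6 of the 25 glutathione genes (list alone 10; adjusted p = 1.0e-17 and 0.0048). At 2 ppm, 15 genes rose and 0 fell, 9 of them by at least 1.5-fold. There Ces1g rose by 1.20 ± 0.18 (adjusted p = 0.00016), Nqo1 by 0.91 ± 0.13 (adjusted p = 0.00014) and Cbr3 by 0.88 ± 0.12 (adjusted p = 8.9e-05). Of the NRF2 targets 10 of 22 rose at 2 ppm (list alone 11; adjusted p = 4.7e-43 and 2.2e-05). At 2 ppm 6 genes passed without the mice with conflicting durations, and 5 without the lettered mice.

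**Figure D3:**
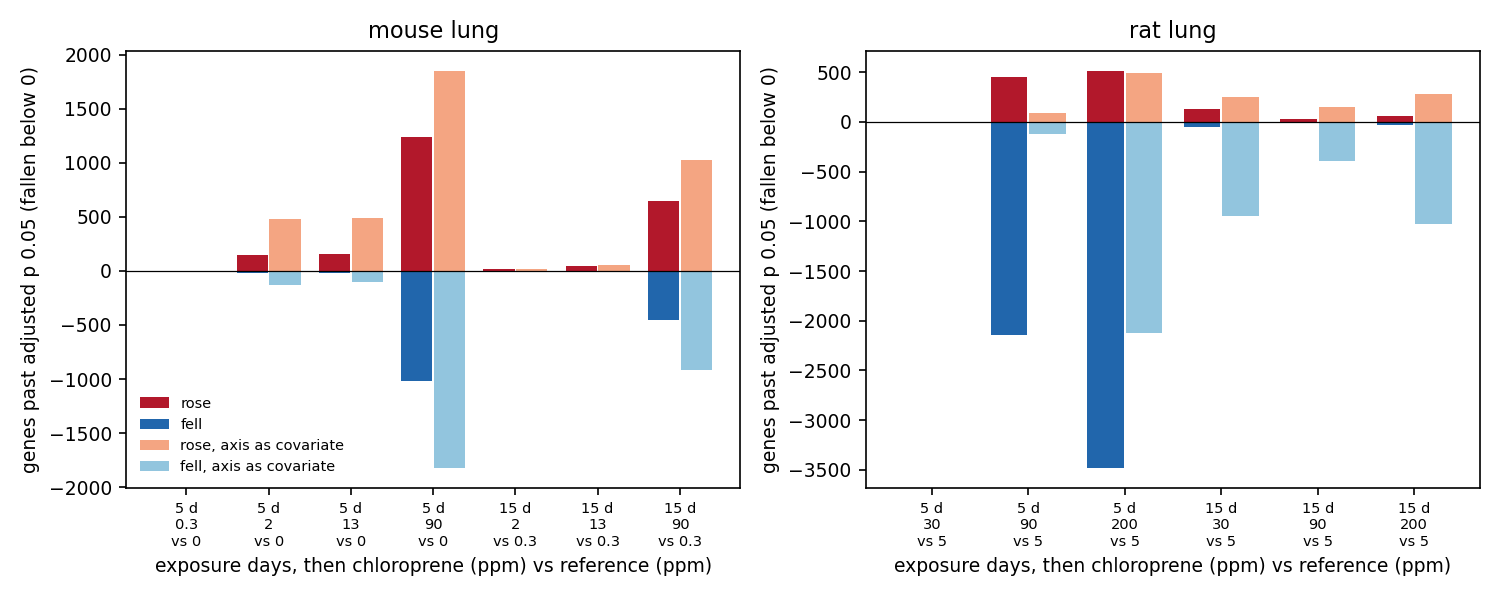
Number of genes past the adjusted threshold for each concentration against its reference, by species and exposure days, counted without a covariate and with the between-array score as covariate. Mouse counts are 2254 at 5 days and 1100 at 15 days for 90 ppm, and rat counts 3992 and 90 for 200 ppm.

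Whether the mouse response differed between the times was tested on the change from 0.3 to 90 ppm at 15 days minus that at 5 days. limma called 6 genes, each with a smaller change at 15 days. Ccno (-1.42 ± 0.20, adjusted p = 0.00012) and Deup1 (-1.12 ± 0.18, adjusted p = 0.0018) act in the formation of multiple cilia. Ccna1 (-1.49 ± 0.21, adjusted p = 0.00012) is a cyclin, and Cdk1 (-1.21 ± 0.23, adjusted p = 0.017) and Aurka (-0.85 ± 0.17, adjusted p = 0.034) are mitotic kinases. Without the mice with conflicting durations 1 gene passed, and without the lettered mice 2 did. The calls at the 2 times overlapped: with 0.3 ppm as reference at both, 722 and 646 genes rose and 370 rose at both (33.8 expected, odds ratio 48.7). In the other direction 638 and 454 fell and 221 fell at both (21.0 expected, odds ratio 29.4, two-sided Fisher exact adjusted p = 4.5e-181).

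In the rat, 200 was compared with 5 ppm after 5 days. The noncoding RNA Xist, which silences an X chromosome, rose 6.23-fold (2.64 ± 0.47, adjusted p = 0.00037). Akr1b8, an aldo-keto reductase and NRF2 target, rose 2.12-fold (1.08 ± 0.14, adjusted p = 4.5e-06), and Gclc 1.68-fold (0.75 ± 0.08, adjusted p = 1.7e-06), each above all reference rats in 5 of 5. Slc7a9, a cystine transporter gene, fell by 1.91 ± 0.26 (adjusted p = 2.8e-05), and Bnc1, a zinc finger gene, by 1.72 ± 0.29 (adjusted p = 0.00027). Wt1, a transcription factor found in mesothelium, fell by 1.26 ± 0.22 and Upk1b, which encodes a uroplakin, by 1.21 ± 0.21, each below all reference rats in 5 of 5. Genes with high rises included Myl7 (2.46 ± 0.80) and Myh6 (2.33 ± 0.69), myosins of the heart, and the secretoglobin Scgb3a1 (2.20 ± 0.66). Others were the vesicle gene Sv2b (2.20 ± 0.41, with another probe set at -0.01), the receptor gene Bmpr2 (1.99 ± 0.34), and the cohesin loader Nipbl (2.14 ± 0.44, above all reference rats in 2 of 5). The neuronal filament gene Prph (-1.45 ± 0.31) and Stmn2 (-1.32 ± 0.25) fell.

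Of 20 NRF2 targets 8 rose and 2 fell (list alone 8 and 2; adjusted p = 2.2e-06 and 0.55). Srxn1, a sulfiredoxin, rose by 0.85 ± 0.16 with another probe set at -0.09, Nqo1 by 0.50 ± 0.10 and Gclm by 0.45 ± 0.10, while Hmox1 was at 0.14 ± 0.14 (adjusted p = 0.42). Of 17 genes of first-phase metabolism 7 rose and 0 fell (list alone 7 and 0; adjusted p = 0.00028 and 0.55). The flavin monooxygenase Fmo2 (1.42 ± 0.29) and Cyp1b1 (0.55 ± 0.10) were among them. Cyp2e1 rose by 0.32 ± 0.13 (adjusted p = 0.049); Cyp2f4 (0.88 ± 0.38, adjusted p = 0.067) and Ephx1 (0.25 ± 0.12, adjusted p = 0.11) did not pass, nor did Cdkn1a (-0.16 ± 0.10, adjusted p = 0.21). Of 10 cardiac muscle genes 5 rose and 0 fell (list alone 6 and 0; adjusted p = 7.4e-05 and 0.60). Their mean score was 0.27 ± 0.60 (SD) at 200 ppm and -0.63 ± 0.22 at 5 ppm. Of 8 erythroid genes 0 rose and 6 fell (list alone 0 and 7; adjusted p = 0.018 and 0.62). Alas2, the haem synthesis enzyme of red cell precursors (-1.21 ± 0.24), and Ahsp (-1.14 ± 0.20) fell. Cholesterol synthesis had 0 rises and 14 falls among 20 (list alone 0 and 15; adjusted p = 0.021 and 0.85), such as Tm7sf2 (-0.52 ± 0.13) and Ebp (-0.42 ± 0.10). Circadian genes had 4 and 3 among 17 (list alone 5 and 3; adjusted p = 0.021 and 0.55), with Per2 at 0.69 ± 0.20 and Npas2 at -0.75 ± 0.15. Club cell genes had 3 and 1 among 13 (list alone 3 and 1; adjusted p = 0.0045 and 0.72), and Scgb1a1 rose by 0.14 ± 0.04. Smooth muscle had 4 and 1 among 11 (list alone 4 and 1; adjusted p = 0.019 and 0.72), with the myosin Myh11 at 0.76 ± 0.15. Fibroblast matrix had 5 and 3 among 25 (list alone 5 and 3; adjusted p = 0.045 and 0.85), with Dcn, decorin, at 1.09 ± 0.20 and the collagen gene Col14a1 at -0.78 ± 0.14. Glucocorticoid genes had 1 and 0 among 13 (list alone 0 and 0; adjusted p = 0.0031 and 0.55). Ciliated cells had 1 and 1 among 13 (list alone 0 and 1; adjusted p = 0.026 and 0.85).

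limma called 3992 genes, 515 higher and 3477 lower, and 387 by at least 1.5-fold; the median change over all genes was -0.14. A single pattern of variation between rats of the same group, given as a score per array, held 64.8% of the variance within groups (40.6% in the mouse). This score averaged 18.2 ± 7.35 (SD) at 200 ppm and -8.38 ± 24.4 at 5 ppm (exact permutation p = 0.0317, adjusted over 12 tests 0.286). With the score as covariate 2611 genes passed, 1905 of the 3992 keeping their call, and without rat 217 of the 5 ppm group 1389 passed. With the score, glutathione genes (0.17, adjusted p = 9.2e-06), endothelium (0.14, 2.2e-05), T and natural killer cells (0.15, 2.2e-05) and immediate early genes (0.08, 0.0036) also passed as higher and alveolar type 1 cells (-0.17, 0.0034) and heat shock (-0.32, 0.0031) as lower. With the 3' to 5' difference the list calls of club cells (adjusted p = 0.050), ciliated cells (0.073), fibroblast matrix (0.057), smooth muscle (0.050), cholesterol synthesis (0.057), circadian clock (0.068) and erythroid cells (0.050) ended. That of fibroblast matrix also ended without a filter (0.072), with the mean of the probe sets (0.087) and with arrays of the same time (0.054). With the 60th percentile cholesterol synthesis ended (0.068) and endothelium passed (0.038). The lists that did not pass were those of endothelium (adjusted p = 0.098), oxidative phosphorylation and glutathione genes (0.18 each), alveolar type 1 cells and heat shock (0.27 each), cell cycle (0.29), T and natural killer cells (0.31) and MHC class II (0.33). Others were immediate early genes (0.37), DNA repair (0.40), mast cells and mucous cells (0.47 each), and B and plasma cells, cytokines and p53 targets (0.52 each). The rest were adipose tissue (0.55), alveolar macrophages (0.57), skeletal muscle, hypoxia and fatty acid oxidation (0.66 each), alveolar type 2 cells, endoplasmic reticulum stress and neutrophils (0.68 each), lipogenesis (0.74) and interferon response (0.82). The basal cell and thymus lists had under 5 measured members in the rat.

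**Figure D4:**
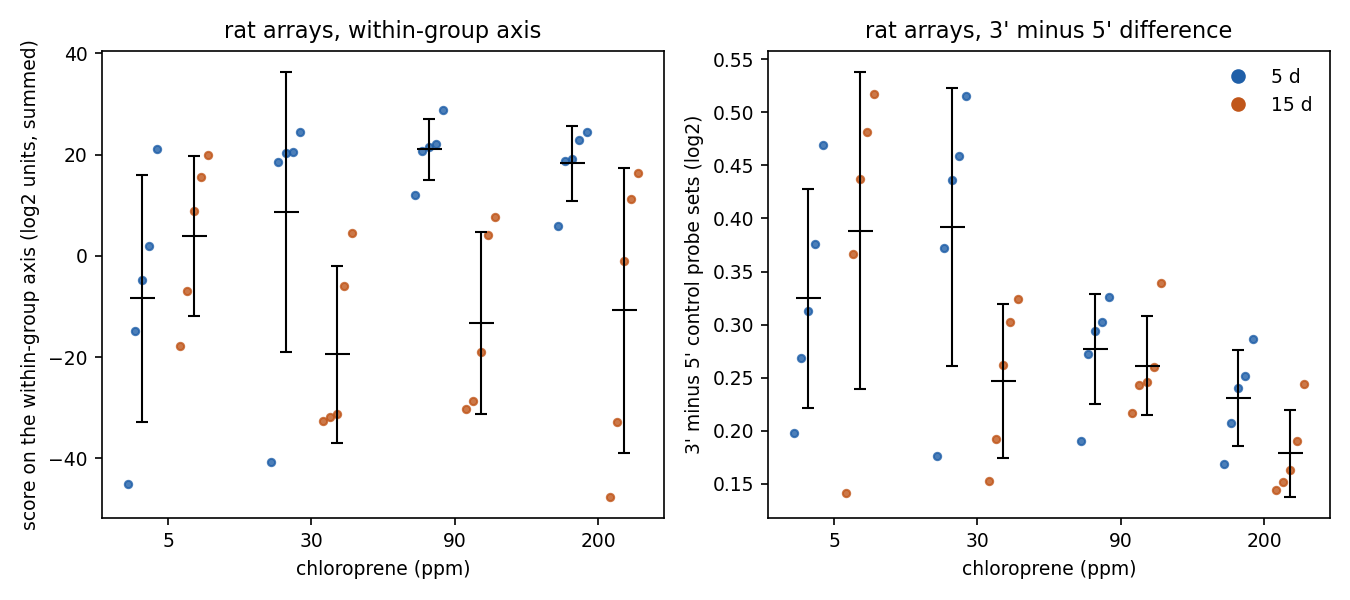
Between-array score of each rat array and difference between the 3' and 5' control probe sets for Gapdh and beta-actin (log2), by chloroprene concentration and exposure time, where points are animals and bars the mean ± SD of 5 animals. After 5 days the score averages 18.2 at 200 ppm and -8.38 at 5 ppm, and after 15 days the control difference averages 0.179 at 200 ppm and 0.389 at 5 ppm.

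At 90 against 5 ppm after 5 days limma called 2598 rat genes, 455 higher and 2143 lower, 305 of them by at least 1.5-fold, with a median change over all genes of -0.14. Xist (2.54 ± 0.47, adjusted p = 0.0033), Myl7 (2.44 ± 0.80, adjusted p = 0.034) and Nipbl (2.26 ± 0.44, above all reference rats in 0 of 5) rose. Slc7a9 (-1.54 ± 0.26, adjusted p = 0.0020), Bnc1 (-1.07 ± 0.29, adjusted p = 0.020) and the sulfotransferase Chst4 (-0.998 ± 0.22, adjusted p = 0.0085) fell. Of 26 interferon response genes 10 rose and 0 fell (list alone 11 and 0; adjusted p = 1.3e-10 and 0.99). The between-array score averaged 21.0 ± 5.98 (SD) in this group. With the score as covariate 211 genes passed, 159 of the 2598 keeping their call, and Myl7 and Bnc1 lost theirs; without rat 217 of the 5 ppm group 36 passed, and with the RNA integrity number as covariate 17. This number was 9.22 ± 0.04 (SD) at 90 ppm and 8.02 ± 0.54 at 5 ppm, with no overlap between the groups. At 30 ppm limma called 0 genes, with 1477 at an unadjusted p under 0.05. The 3 genes with the smallest p were the receptor gene Plxnc1 (0.44 ± 0.09, adjusted p = 0.14), the sestrin Sesn3 (-0.46 ± 0.09, adjusted p = 0.14) and the kinase gene Stk25 (-0.52 ± 0.11, adjusted p = 0.20). Without rat 239 of the 30 ppm group 281 genes passed.

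After 15 days 200 was again compared with 5 ppm in the rat. Akr1b8 rose 2.00-fold (1.00 ± 0.14, adjusted p = 0.00014), the glutathione transferase Gsta3 2.04-fold (1.03 ± 0.17, adjusted p = 0.00092) and Gclc 1.44-fold (0.52 ± 0.08, adjusted p = 0.00086). Tbc1d12, a regulator of small GTPases, rose 3.25-fold (1.70 ± 0.26, adjusted p = 0.00040), and the transcription factor Nfix 2.57-fold (1.36 ± 0.29, adjusted p = 0.015). Scn3b, a sodium channel subunit gene, fell by 0.72 ± 0.14, and Cd93, a receptor on endothelium, fell by 0.56 ± 0.11, with another probe set of Cd93 at 0.03. Of 20 NRF2 targets 9 rose and 0 fell (list alone 17 and 0; adjusted p = 6.6e-19 and 0.031). Glutathione reductase, Gsr, rose by 1.14 ± 0.23, Srxn1 by 0.96 ± 0.16, Nqo1 by 0.64 ± 0.10, Txnrd1 by 0.52 ± 0.07 and Gclm by 0.43 ± 0.10. Of 25 glutathione genes 5 rose and 0 fell (list alone 10 and 0; adjusted p = 3.0e-10 and 0.59), including Gstp1 (0.62 ± 0.13), Gstt2 (0.60 ± 0.13) and Gsta1 (0.42 ± 0.07). Of 35 cell cycle genes 0 rose and 1 fell (list alone 0 and 5; adjusted p = 0.00017 and 0.70): Cks2, a subunit of cyclin-dependent kinases, fell by 0.59 ± 0.12. Mast cell genes had 1 rise and 0 falls among 9 (list alone 2 and 0; adjusted p = 0.026 and 0.59), the receptor gene Il1rl1 at 0.27 ± 0.07.

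The remaining rat lists that passed as higher after 15 days had 0 rises and 0 falls: club cells (adjusted p = 0.0055 and 0.70), cardiac muscle (0.0065 and 0.70), first-phase metabolism (0.012 and 0.70), MHC class II (0.026 and 0.84) and glucocorticoid response (0.044 and 0.70). Adjusted over the list alone, club cells, cardiac muscle and MHC class II had 1 rise each. Cyp2e1 (0.30 ± 0.13, adjusted p = 0.21), Cyp2f4 (-0.14 ± 0.38, adjusted p = 0.88), and Ephx1 (0.29 ± 0.12, adjusted p = 0.21) did not pass. Nor did Hmox1 (0.43 ± 0.14, adjusted p = 0.11), Scgb1a1 (0.01 ± 0.04, adjusted p = 0.93) and Cdkn1a (-0.00 ± 0.10, adjusted p = 0.99), and Mki67 was below the signal filter in the rat. limma called 90 genes, 55 higher and 35 lower, and 25 by at least 1.5-fold. With the between-array score as covariate 277 were higher and 1029 lower, and leaving out 1 rat gave 15 to 275 genes. The difference between the 3' and 5' control probe sets was 0.179 ± 0.0406 (SD) at 200 ppm and 0.389 ± 0.149 at 5 ppm (exact permutation p = 0.0476, adjusted over 12 tests 0.286). With this difference as covariate 3 genes passed, Gsta3, Akr1b8 and Gclc. With the RNA integrity number as covariate 20 passed. The interferon response list passed as higher under 6 alternatives: with the 3' to 5' difference (0.29, adjusted p = 3.4e-09), the between-array score (0.0034), its mouse-weighted form (0.0035), arrays of the same time (0.011) or the 60th percentile (0.038), and without the 3 rats whose title lacks the tissue (0.023). With the 3' to 5' difference lipogenesis (0.0042), circadian clock (0.0085) and skeletal muscle (0.010) also passed as higher and neutrophils (-0.44, 0.020) and endothelium (-0.13, 0.032) as lower, while MHC class II ended (0.10). Oxidative phosphorylation passed with the 60th percentile (0.038), the score (0.0497), its mouse-weighted form (0.046) and without these 3 rats (0.043), circadian clock with the score (0.046), and lipogenesis with the mean of the probe sets (0.023). Without a filter mucous cells (0.042), skeletal muscle and adipose tissue (0.024 each) passed. Mast cells ended with the RNA integrity number (0.060), the 60th percentile (0.35) and no filter (0.20), MHC class II (0.13) and glucocorticoid response (0.12) with quantile normalization, and first-phase metabolism (0.061) and club cells (0.14) without these 3 rats. Lists that did not pass were interferon response and oxidative phosphorylation (adjusted p = 0.10 each), lipogenesis, adipose tissue and circadian clock (0.12 each), and skeletal muscle (0.12). Others were fibroblast matrix and alveolar type 2 cells (0.35 each), B and plasma cells, immediate early genes, smooth muscle, erythroid cells and mucous cells (0.52 each), and T and natural killer cells and fatty acid oxidation (0.53 each). The rest were neutrophils, ciliated cells, DNA repair and endoplasmic reticulum stress (0.76 each), alveolar macrophages and endothelium (0.79 each), alveolar type 1 cells (0.84), cytokines and heat shock (0.85 each), and hypoxia, p53 targets and cholesterol synthesis (0.98 each).

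At 90 ppm after 15 days 34 rat genes passed, 30 higher and 4 lower, and 13 by at least 1.5-fold. Tbc1d12 (1.53 ± 0.26, adjusted p = 0.0044), Nfix (1.39 ± 0.29) and Gsr (1.10 ± 0.23) rose. Adam33 (-0.40 ± 0.09), the interferon regulatory factor Irf3 (-0.37 ± 0.08) and Gnb1, a G protein subunit gene (-0.32 ± 0.07), fell, although other probe sets of Gnb1 were at 0.63 and 0.14. At 30 ppm 183 passed, 126 higher and 57 lower, and 29 by at least 1.5-fold. With the between-array score as covariate 245 rose and 944 fell. Nfix (1.45 ± 0.29, adjusted p = 0.014), Gsr (1.09 ± 0.23) and Crim1 (1.08 ± 0.29) rose. Nek1 (-1.47 ± 0.32, adjusted p = 0.024), Ryr3 (-1.03 ± 0.25) and Ube3al1 (-1.09 ± 0.30) fell. With the RNA integrity number or the 3' to 5' difference as covariate limma called 0 genes at either concentration. Without a covariate 1490 genes at 90 ppm and 2831 at 30 ppm had an unadjusted p under 0.05. The RNA integrity number averaged 8.42 ± 0.23 (SD) at 90 ppm, 8.32 ± 0.50 at 30 ppm and 9.02 ± 0.43 at 5 ppm. In the 5 ppm group, leaving out rat 225 left 2 genes at 30 ppm and leaving out rat 227 left 2 at 90 ppm.

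For the rat, the change from 5 to 200 ppm differed between 15 and 5 days in 1259 genes, 970 with a more positive and 289 with a more negative difference, and 464 of at least 1.5-fold, with a median over all genes of 0.15. The named genes, each at adjusted p = 0.030, were Slc7a9 (1.81 ± 0.37), the mitochondrial ribosome gene Mrps18c (1.01 ± 0.19), the kinase gene Camk2b (0.71 ± 0.15), the actin-binding gene Avil (0.71 ± 0.14) and the desmosome gene Pkp2 (0.70 ± 0.14) on the positive side. Those on the negative side were Myh11 (-1.02 ± 0.22), the transporter gene Abca8a (-0.88 ± 0.19), Prom1 (-0.71 ± 0.15), the channel gene Pkd2 (-0.57 ± 0.12) and Etfbkmt (-0.53 ± 0.10). With the between-array score, the RNA integrity number or the 3' to 5' difference as covariate, or without the 3 rats whose title lacks the tissue, limma called 0 genes, against 4972 genes at an unadjusted p under 0.05 without a covariate. Calls at the 2 times shared 22 rises (2.57 expected, odds ratio 14.1, two-sided Fisher exact adjusted p = 4.4e-15), among them Akr1b8, Gsta3, Srxn1, Gclc, Nqo1, Gclm, Txnrd1, Tbc1d12 and Nfix. They shared 14 falls (11.1 expected, adjusted p = 0.34 by the same exact test).

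The species were set side by side through their calls, since their tables were normalized separately, over 9608 genes with identical symbols. After 15 days at the highest concentrations, 90 ppm in the mouse and 200 ppm in the rat, 15 genes rose in both (2.12 expected, odds ratio 10.2, two-sided Fisher exact adjusted p = 3.2e-09). They were Gsta3, Akr1b8, Srxn1, Gsr, Nqo1, Gclc, Txnrd1, Abcc3, Gpx2, Entpd5, Gclm, Pgd, Gstp1, Tgfbr3 and Zbtb14. Falls shared at that time numbered 3 (1.06 expected, exact adjusted p = 0.13). After 5 days at these concentrations 45 genes rose in both species (40.5 expected, exact adjusted p = 0.49), among them Akr1b8, Gsta3, Srxn1, Gclc, Nqo1 and Gclm. In addition 167 fell in both, fewer than the 234 expected (odds ratio 0.61, exact adjusted p = 3.2e-08). Restricted to changes of at least 1.5-fold after 5 days, 10 rose in both (3.64 expected, exact adjusted p = 0.0070) and 11 fell in both (2.89 expected, exact adjusted p = 0.00035), which turned the direction for the falls. These shared falls rest on rat calls of which, with the between-array score as covariate, 1905 of 3992 at 200 ppm and 159 of 2598 at 90 ppm were kept, and on a median rat change over all genes of -0.14 at each. At 90 ppm in both species, 25 shared rises (35.8 expected, exact adjusted p = 0.10) and 89 shared falls (144 expected, odds ratio 0.54, exact adjusted p = 4.5e-08) were found after 5 days. After 15 days 3 rises (1.24 expected, exact adjusted p = 0.17) and 0 falls (0.141 expected, exact p = 1) were shared.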

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

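The between-array scores as covariate, the letter as a block and the tests of array measures and list scores were chosen after seeing the results. So were all ratios and shares that weigh an explanation. The other tests given here were chosen in advance.

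For each comparison, 100 of the 126 possible splits of its 10 arrays into groups of 5 (100 of 31752 for the differences between times) were fitted, the real one included. In the mouse after 5 days only the real split gave as many genes at 2 ppm (166, highest other 7). The same held at 13 ppm (179, highest other 92) and 90 ppm (2254, highest other 713), which argues against chance. After 15 days 4 splits gave as many at 2 ppm (15, highest other 953) and 2 at 13 ppm (45, highest other 47). At 90 ppm 2 did (1100, highest other 1899). The shares are under 0.05, but as another split called more, chance stays open. The highest other split put every lettered mouse on the same side, 3 at 2 ppm, 2 at 13 ppm and 4 at 90 ppm. At 2 ppm it far exceeded the real count, which points to a structure that follows the letter. With the letter as a block 14, 36 and 1204 genes passed, and without the lettered mice 5, 32 and 501. For the mouse difference between times 11 splits gave at least the 6 genes called (highest other 1672, with 3 of the 4 lettered mice of the 15-day groups on the same side, and 5 lettered mice in all 4 groups), so chance was not excluded and a structure of the samples showed here too. At 0.3 ppm after 5 days limma called 0 genes (514 at an unadjusted p under 0.05), and the highest other split also gave 0. Every split gives at least 0, so this says nothing about chance there.

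In the rat after 5 days 2 splits gave as many genes at 90 ppm (2598, highest other 4951) and 1 at 200 ppm (3992, highest other 2926). After 15 days 1 split gave as many at 30 ppm (183, highest other 57), 1 at 90 ppm (34, highest other 20) and 2 at 200 ppm (90, highest other 3285), and 2 did for the difference between times (1259, highest other 7321). Where only the real split gave as many genes, this argues against chance. Where another split called more, chance stays open, although the share is under 0.05. At 30 ppm after 5 days limma called 0 genes, with 1477 at an unadjusted p under 0.05, and the highest other split gave 5533. Every split gives at least 0, so the splits say nothing about chance there. Splits that call so many genes point to a structure of the rat arrays other than the exposure groups.

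After 5 days the rats at 90 and 200 ppm had many lower genes (3477 at 200 ppm) and high between-array scores, and the RNA integrity numbers at 90 ppm (9.2 to 9.3) did not overlap those at 5 ppm (7.3 to 8.5). The tables argue against RNA integrity as the whole cause of the 2598 calls at 90 ppm, as far as its slope within groups also holds between them: with it as covariate their median signed change was 1.01 times as large (SD 0.215 with the numbers permuted within groups), 17 calls were kept because the standard error grew (0.11 before and 0.14 after), and it did not follow the score within groups (r = 0.0391 over 38 arrays, permutation p = 0.842). Labelling and hybridization are a candidate source of the score. It fell with the poly-A spike-in controls (r = -0.655 over 40 arrays, permutation p = 0.00037, adjusted over 6 relations 0.0022). Spearman's rho was -0.566, and r was -0.564 without the 2 farthest arrays. The mouse score did not fall with the controls (r = -0.0729, permutation p = 0.691). Its gene weights correlated with those of the rat at r = 0.860, so this source stays open. With the mouse-weighted score as covariate 5.16% of the calls at 90 ppm remained (134 of 2598, median size 0.35 before and 0.13 after, standard error 0.11 and 0.07). At 200 ppm 42.5% remained (1695 of 3992, median size 0.35 before and 0.17 after, standard error 0.11 and 0.07). For calls that ended at 90 or 200 ppm, exposure and the score cannot be told apart, as the mean scores lay apart. They were 21.0 and 18.2 against -8.38 at 5 ppm, at 200 ppm not past adjustment (exact permutation p = 0.0317, adjusted over 12 tests 0.286). At 200 ppm after 15 days the 3' to 5' difference as covariate left 0.616 of the median change of the 90 called genes (0.43 before and 0.26 after, standard error 0.09 and 0.10); Gsta3, Akr1b8 and Gclc kept their calls, and for the calls that ended exposure and RNA or labelling quality cannot be told apart, because the mean control differences lay apart (0.179 against 0.389 at 5 ppm), though not past adjustment (exact permutation p = 0.0476, adjusted over 12 tests 0.286).

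In the mice after 5 days the scores of the B and plasma cell list and of the T and natural killer cell list were lower at 90 than at 0 ppm, with differences of -0.85 and -0.57 (exact permutation p = 0.00794 each, adjusted over 8 tests 0.0317 each). The tables argue against the between-array score: with it as covariate the change of the B cell list was 1.01 times as large (-0.86). High values of the 0 ppm mice are a candidate explanation for part of it: against 0.3 ppm the B cell change was 0.430 of that against 0 ppm (-0.37, exact permutation p = 0.0794, adjusted 0.0907), and the 0.3 ppm mice themselves lay at -0.49 from the 0 ppm mice (exact permutation p = 0.0397, adjusted 0.0635). The T and natural killer cell change against 0.3 ppm was -0.44 (exact permutation p = 0.0397, adjusted 0.0635), and after 15 days the changes were -0.40 (exact permutation p = 0.0635, adjusted 0.0847) and -0.36 (exact permutation p = 0.0317, adjusted 0.0635). A loss of lymphocytes from the lung and lower expression per cell stay open, untested. A shift at 0.3 ppm, not past adjustment in these tests, stays open.

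At 5 days Ccno (1.55), Deup1 (1.52), Ccna1 (2.10), Cdk1 (0.93) and Aurka (0.80) rose at 90 against 0 ppm, while at 15 days, against 0.3 ppm, Ccna1 rose (0.60, adjusted p = 0.0060) and Ccno (0.08), Deup1 (0.30), Cdk1 (-0.12) and Aurka (-0.14) did not pass (adjusted p from 0.18 for Deup1 to 0.86 for Ccno). As the 6 genes were chosen with all mice, only the size of their mean difference was tested. It was 0.989 times as large without the lettered mice and 1.01 times without those with conflicting durations. The tables argue against the between-array score (0.931 with it as covariate, all 6 genes called). Without the lettered mice 2 of the 6 calls were kept and without those with conflicting durations 1 was, because the spread grew with fewer mice: the mean difference of the 6 genes was -1.26 (mean standard error 0.215) before, and -1.24 (0.258) and -1.27 (0.283) after. A biological difference between the times stays open and untested, and chance was not excluded for the count. The proliferation marker Mki67 was at 0.05 ± 0.24 at 5 days.

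Among 311 groups of 5 searched for an animal far from the other 4, 21 had one, and chance gives about 1 in 20, or 15.6 here. Of the array measures, the 3' to 5' control difference of mouse 105 (0 ppm, 5 days) was 0.0121, against 0.208 to 0.272 in the others, and the between-array score of rat 239 (30 ppm, 5 days) was -40.7, against 18.6 to 24.4. The RNA integrity number was 8.6 in mouse 179 (90 ppm, 15 days; 9.5 to 9.7 in the others), 8.3 in mouse 167 (90 ppm, 5 days; 9.1 to 9.3) and 9.3 in rat 249 (90 ppm, 5 days; 9.2 in each other). Of the list scores, that of ciliated cells was -0.40 in mouse 117 (0.3 ppm, 5 days; -0.07 to 0.02 in the others) and 0.21 in mouse 128 (0.3 ppm, 15 days; -0.29 to -0.17). The cardiac muscle score was 0.57 in mouse 157 (13 ppm, 15 days; -0.26 to -0.07) and -0.80 in rat 266 (200 ppm, 5 days; 0.48 to 0.65), and the NRF2 score was 0.46 in rat 277 (200 ppm, 15 days; 0.16 to 0.23).

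Single genes lay far from the other 4 animals as well. In the mouse these were, at 5 days, Cyp2e1 at 9.53 (10.08 to 10.18 in the others) and Hmox1 at 10.96 (9.98 to 10.03), both in mouse 137 at 2 ppm, Cyp2f2 at 14.79 in mouse 117 at 0.3 ppm (14.89 to 14.92) and Scgb1a1 at 15.32 in mouse 103 at 0 ppm (15.23 to 15.25). At 15 days they were Gclm at 9.98 in mouse 127 at 0.3 ppm (10.24 to 10.32) and Nqo1 at 9.14 in mouse 160 at 13 ppm (9.28 to 9.33). In the rat at 15 days Cyp2f4 was at 9.88 in rat 245 at 30 ppm (11.10 to 11.50), and rat 228 at 5 ppm had Cyp2f4 at 11.26 (10.49 to 10.70) and Gclm at 8.82 (8.41 to 8.53). Gclc was at 8.94 in rat 282 at 200 ppm after 15 days (9.39 to 9.46), and Hmox1 at 9.67 in rat 217 at 5 ppm after 5 days (9.09 to 9.22).

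The test of the difference between the times gave -0.85 (Aurka), -1.12 (Deup1), -1.21 (Cdk1), -1.42 (Ccno) and -1.49 (Ccna1) in the mouse. Chance was not excluded there. In the rat it gave 1.81 (Slc7a9), 1.01 (Mrps18c), 0.71 (Camk2b, Avil), 0.70 (Pkp2), -0.53 (Etfbkmt), -0.57 (Pkd2), -0.71 (Prom1), -0.88 (Abca8a) and -1.02 (Myh11). Each rat call ended with any covariate tried. Probe sets without a gene symbol were used in no comparison of genes. Of 3820 such probe sets in the mouse, 274 passed the threshold at 90 against 0 ppm after 5 days, 133 higher and 141 lower, and 113 passed at 90 against 0.3 ppm after 15 days. Of 4436 in the rat, 1072 passed at 200 ppm after 5 days and 162 after 15 days.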

How the results depend on the processing

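The alternatives named above as chosen after seeing the data are among those given here. No paired analysis was possible because the groups compared share no replicate numbers. The number of arrays and the signal over background limit what was seen: genes whose probe sets stayed under the signal filter were not tested, and limma tested fewer or more genes where the filter changed. The number of genes at 13 ppm after 15 days in the mouse stayed within 1.5 times its value of 45 under all 12 alternatives (32 to 56). The mouse counts at 90 ppm did so under 9 of 12 alternatives at each time (1987 to 2504 after 5 days, 803 to 1204 after 15 days), that at 13 ppm after 5 days under 9 of 12 (161 to 234) and that at 2 ppm after 15 days under 10 of 12 (10 to 16). The count at 2 ppm after 5 days did so under 5 of 12 (124 to 177) and left that range under the other 7. In the rat the count at 200 ppm after 5 days lay between 3409 and 5857 under 8 of 11. With calls of at least 1.5-fold the 2 times shared 84 rises and 59 falls in the mouse and 10 rises in the rat, and the species shared 5 rises after 15 days at the highest concentrations, all on the same side of the threshold as before. Of the values of named genes, 371 kept their side with quantile normalization, 7 lost and 6 gained it; with the between-array score as covariate these numbers were 342, 17 and 25. With the RNA integrity number 297 kept and 87 lost it, and with the 3' to 5' difference 326 kept, 56 lost and 2 gained it. Leaving out 1 animal kept 3482 such values on their side, with 466 lost and 42 gained.

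With the RNA integrity number as covariate, which leaves out 7 arrays, 3 of them among the 5 mice at 0 ppm, 7, 34 and 761 mouse genes passed at 2, 13 and 90 ppm after 5 days. In the rat 17 and 2468 passed at 90 and 200 ppm after 5 days, 0, 0 and 20 at 30, 90 and 200 ppm after 15 days, and 0 for the difference between times (limma; where 0 passed, 2831 at 30 ppm, 1490 at 90 ppm and 4972 for the difference had an unadjusted p under 0.05 without the covariate). In the mouse fewer samples are part of the cause. In the rat groups at 5 and 90 ppm after 5 days and in all rat groups after 15 days no array was left out. There the median change of the called genes was 0.35 before and 0.35 after at 90 ppm after 5 days (standard error 0.11 and 0.14), 0.35 and 0.34 at 30 ppm (0.08 and 0.09), 0.46 and 0.41 at 90 ppm (0.10 and 0.10) and 0.43 and 0.40 at 200 ppm (0.09 and 0.10) after 15 days, and the cause was not tested further. With the 3' to 5' difference 58 passed at 2 ppm in the mouse after 5 days, 5211 at 90 ppm in the rat after 5 days, 0, 0 and 3 after 15 days and 0 for the difference between times. The rat lists past the threshold then numbered 4 after 5 days and 14 after 15 days, and the neutrophil list at 200 ppm after 15 days turned to -0.44. The cause was not tested. With arrays of the same time only, hence fewer samples for the spread, 1 gene passed at 0.3 ppm and 272 at 2 ppm in the mouse after 5 days, and 59 at 30 ppm in the rat after 15 days. With 0.3 ppm as reference 11, 48 and 1360 passed at 2, 13 and 90 ppm after 5 days, Zbtb16 at 2 ppm turned to -0.036 and the heat shock list at 90 ppm to -0.51. Of the 18 list calls at 90 ppm 14 were kept. The cause was not tested.

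Without the mice with conflicting durations, hence with fewer samples, 6 and 530 genes passed at 2 and 90 ppm after 15 days and 1 for the difference between times; the lists of fatty acid oxidation (0.20), oxidative phosphorylation (0.091), skeletal muscle (0.086) and adipose tissue (0.39) turned to higher. Of the 24 list calls 17 were kept. Without the lettered mice 318 passed at 2 ppm after 5 days, 5 and 501 at 2 and 90 ppm after 15 days and 2 for the difference between times; fatty acid oxidation (0.11), oxidative phosphorylation (0.0049) and adipose tissue (0.13) turned, and again 17 of 24 list calls were kept. With 1 animal left out fatty acid oxidation ranged from -0.190 (without reference mouse 129) to 0.0578 and oxidative phosphorylation from -0.133 to 0.0138, both turned without reference mouse 127. With the letter as a block 276 passed at 2 ppm after 5 days. With the between-array score as covariate 610, 588 and 3673 mouse genes passed at 2, 13 and 90 ppm after 5 days and 1936 at 90 ppm after 15 days. Rat counts with it were 211 and 2611 at 90 and 200 ppm after 5 days, 1189, 545 and 1306 at 30, 90 and 200 ppm after 15 days and 0 for the difference between times, and 17 lists passed after 5 days. With the mouse weights they were 208, 2496, 1183, 518, 1355, 0 and 17 in the same order. Without the 3 rats whose title lacks the tissue 1246 and 4780 passed at 30 and 90 ppm after 5 days, 1260, 228 and 197 at 30, 90 and 200 ppm after 15 days and 0 for the difference between times. The cause was not tested.

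At 30 ppm in the rat after 15 days 422 genes passed without a filter (more genes tested), 41 with the 60th percentile (fewer genes tested) and 283 with quantile normalization. With the mean of the probe sets 148 passed at 200 ppm and Gnb1 at 90 ppm turned to 0.15. With an estimated correlation 3 lists passed at 90 ppm after 5 days and 4 after 15 days in the mouse, and 0 and 1 at 200 ppm in the rat (camera; 11 and 9 at the preset correlation). Restricted to 1.5-fold, the falls shared by the species after 5 days turned from fewer to more than expected, 11 at the highest concentrations and 2 at 90 ppm, 10 rises shared after 5 days passed, and 1 fall shared after 15 days passed. Other probe sets of a gene turned for Ackr4 (0.14 and 0.056 at 13 ppm), Mt1 (-0.011 at 5 and -0.025 at 15 days), Hsd17b7 (0.070), Plk2 (0.13), Ms4a4b (0.013) and Scn3a (0.13) in the mouse after 5 days. After 15 days they turned for Cep57l1 (0.048 and 0.11), Lox (-0.012), Ddx58 (0.024), Msmo1 (0.067), Lss (0.0074), Acly (0.0021), Acaca (0.10), Xaf1 (0.11) and Nr4a3 (0.039). In the rat they turned for Sv2b (-0.0066), Srxn1 (-0.094), Hlf (-0.0076), Srebf2 (0.12), Gnb1 (0.63 and 0.14), Ankrd6 (0.22), Ube2n (0.12) and Cd93 (0.026). The cause was not tested.

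Leaving out 1 animal gave these ranges in the mouse after 5 days: 0 to 0 genes at 0.3 ppm (limma, 514 at an unadjusted p under 0.05 with all animals), 34 to 233 at 2 ppm, 81 to 363 at 13 ppm, 1822 to 2242 at 90 ppm and 16 to 19 lists. At 2 ppm the counts were 34 and 42 without mice 136 and 137, and 70, 62, 45 and 61 without reference mice 101, 102, 103 and 105. At 13 ppm they were 363, 81 and 86 without mice 149, 151 and 154, and 118 and 115 without reference mice 101 and 103. After 15 days the ranges were 8 to 17 at 2 ppm (9 without mouse 144, 8 without reference mouse 126 or 129), 35 to 62 at 13 ppm, 666 (without mouse 180) to 1221 at 90 ppm and 20 to 24 lists. For the difference between times they were 3 to 11: 3 without mouse 118, 121, 129, 165 or 180, and 11 without mouse 167.

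In the rat after 5 days the ranges were 0 to 281 at 30 ppm (281 without rat 239, 1 without rat 234 or 220), 36 to 5639 at 90 ppm, 1389 to 5581 at 200 ppm (2661 without rat 266) and 8 to 15 lists. Without reference rats 217, 219, 221 and 222 in turn 36, 459, 943 and 5639 passed at 90 ppm, and without rats 250, 251, 252 and 253 there 688, 480, 1057 and 847; without rat 217 1389 passed at 200 ppm. After 15 days they were 2 to 415 at 30 ppm, 2 to 143 at 90 ppm, 15 to 275 at 200 ppm and 6 to 10 lists. Without reference rats 225, 226, 227, 228 and 229 in turn 2, 415, 9, 34 and 19 passed at 30 ppm, 3, 143, 2, 5 and 9 at 90 ppm, and 15, 275, 23, 38 and 58 at 200 ppm. Without rats 241, 242, 243 and 245 of the 30 ppm group 11, 10, 85 and 80 passed there, without rats 257, 258, 259, 260 and 261 of the 90 ppm group 2, 3, 3, 9 and 14, and without rats 277, 279 and 280 of the 200 ppm group 40, 152 and 37. The difference between times ranged from 0 to 4707: 0 without rat 217, 227, 229, 269 or 277, 1 without 282, 22 without 221, 25 without 219, 27 without 225, 29 without 266, 433 without 265, 530 without 268, 1893 without 220, 1896 without 267, 3144 without 228, 3752 without 281, 4172 without 279 and 4707 without 222. Each of these fits had fewer samples, and the cause was not tested further.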

Other observations

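The genes in this part that the report does not name, and the values given here, were chosen after they were seen, and no hypothesis was tested on them. In the mouse after 5 days at 90 against 0 ppm, genes of the circadian clock moved both ways: the repressor Nr1d1 was at -1.72, its partner Nr1d2 at -0.53 and the output factor Dbp at -1.49, while Cry1 was at 1.46, Nfil3 at 0.89, Per2 at 0.81, Arntl at 0.52 and Cry2 at 0.50. Of the list, 5 rose and 3 fell (7 and 4 adjusted over the list alone), and as a whole it did not pass (adjusted p = 0.73).

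At the lower concentrations after 5 days the mean change of the heat shock list was 0.53 at 0.3 ppm (adjusted p = 4.2e-18, but 0.092 with an estimated correlation), 0.68 at 2 ppm (2.2e-14, but 0.099) and 0.69 at 13 ppm (2.9e-16, but 0.069), and 0.02 at 90 ppm (0.73). Over the 18 genes, 0, 7 and 6 rose at 0.3, 2 and 13 ppm. The B and plasma cell list was at -0.49 at 0.3 ppm (adjusted p = 3.3e-18, but 0.092 with an estimated correlation), -0.58 at 2 ppm and -0.49 at 13 ppm. Limma called 0 genes at 0.3 ppm, with 514 at an unadjusted p under 0.05.

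After 5 days rat Slc7a9 (7.64, 6.72, 6.09, 5.73) and Bnc1 (7.09, 6.46, 6.02, 5.37) stepped down over 5, 30, 90 and 200 ppm. So did Wt1 (7.92, 7.47, 7.07, 6.66) and Upk1b (10.80, 10.35, 9.85, 9.58). After 15 days Slc7a9 (6.76, 6.79, 6.79, 6.67), Bnc1 (6.68, 6.44, 6.48, 6.45) and Upk1b (10.38, 10.42, 10.30, 10.40) did not. The 5-day between-array score was lowest at 5 ppm, so exposure was not told apart from it. Within groups the between-array score of the mouse had r = -0.238 with the RNA integrity number (permutation p = 0.279, adjusted over 6 relations 0.558) and 0.141 with the 3' to 5' difference. In the rat r with the 3' to 5' difference was 0.393 (permutation p = 0.0369, adjusted 0.111, and 0.217 without the 2 farthest arrays).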
